A study of Mus musculus with 2 samples.

How the data were processed

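Cells isolated from the dorsal dermis of newborn C57BL/6 mice were grown in culture and transfected with a control small interfering RNA (siRNA) or with siRNAs against β-catenin, the protein product of Ctnnb1. An siRNA is a short RNA duplex that directs cleavage of a matching messenger RNA. Per the labels' protocols, the cells were cultured for 24 h before transfection, the siRNA was used at 10 nM for 48 h, and 300 ng of total RNA was labelled for an Affymetrix whole-transcript array. There was 1 array per group, so 2 arrays in all. Nothing in the labels says how many cultures or pups stood behind each array.

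The deposited table holds 1 value per probe set and array on the log2 scale. Robust multi-array average (RMA), a method that subtracts background, makes the distributions of the arrays equal and summarises the probes of a probe set, is the only tool named, per the submitters' processing notes. The software, its version and any filter are not given in the sources used here. That the deposited values are log2 was judged from their range, from 0.485 to 13.5. The sorted values of the 2 columns differed by at most 0.123, as equalised distributions do. RMA of this kind removes an overall difference in RNA yield between the cultures, so each difference below is relative to the other probe sets. It also shrinks differences of dim probe sets towards 0, since background signal is left in both values. Detection calls and probe intensities were not used here, so no value can be called above or below background by the array's own measure.

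The table has 28944 probe sets. The platform annotation gave 1 gene symbol for 21789 of them, several for 1621 and none for 5534. Gene identifiers of 21698 single-symbol probe sets were found in a RefSeq table of GRCm38.p6, from which current symbols were taken, and the other 91 kept the annotation's symbol. Older symbols in the gene lists were matched through that table's synonyms. Probe sets with several symbols or none were left out of the gene comparison. No genome build is named for the array values, so coordinates are not given. Where a gene had more than 1 probe set (999 of 19938 genes), the probe set with the highest mean of the 2 arrays stood for it.

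For each gene the log2 value of the control array was subtracted from that of the β-catenin siRNA array. Genes were kept if the higher of their 2 values was at or above the median of all gene means, 5.13 on the log2 scale, which left 10197 genes. Sizes of 2-fold and 1.5-fold were the only criteria for counting genes. With 1 array per group there is no replicate error, so no p-value, standard error or standard deviation is given, and leaving out a replicate was not possible. As a guide to scale only, the robust SD (1.4826 times the median absolute deviation) of the difference over all kept genes was 0.22, and the pooled SD of the difference between probe sets of the same gene, over 582 genes, was 0.16. The robust SD mixes array noise, differences between the cultures and any effect of the siRNA, which cannot be told apart. The SD between probe sets leaves out differences between cultures that the probe sets of a gene share.

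Gene lists (43 lists, 37 of them with at least 5 kept members) were fixed before the data were examined, as were the level filter, the fold sizes, the alternatives and the rule for naming genes. The median difference of a list was set against the medians of 10000 random lists of the same size, drawn within 20 bins of mean level from kept genes with a plain symbol, with replacement within a bin. A list was described as outside the random range when its median lay below the 2.5th or above the 97.5th percentile. This percentile describes these 2 arrays. It is not a p-value, and random lists lack the co-regulation that members of a pathway share. Genes were named if they were the target, among the 15 largest differences in either direction (leaving out predicted genes, clone names, olfactory, vomeronasal and taste receptors and small RNAs), or among the 4 largest absolute differences of kept members in a list. Families of genes sharing a symbol stem, with at least 8 kept members, were scored the same way for the closing observations.

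On simulated differences for control against β-catenin siRNA, with the observed robust SD at each level over 10197 genes, with normally distributed noise and 50 genes per fold size, the 2-fold rule found 100% of genes simulated at 3-fold, 50% at 2-fold and 0.090% of unchanged genes. The 1.5-fold rule found 98% at 2-fold, 52% at 1.5-fold and 1.45% of unchanged genes. These rates hold for the simulated noise only. They do not give the share of counted genes that would differ between 2 cultures without any change in β-catenin. Of 200 simulated lists of 25 unchanged genes, 7.5% lay outside the random range, and of 200 lists shifted by 0.3, 100% did.

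Alternatives were lowess centring of the differences on level (span 0.3), median centring, the mean of all probe sets of a gene, no level filter, a filter at the 75th percentile of gene means (7.12), an added requirement of 4 robust SDs at similar level, the mean of a list in place of its median, 50 bins, and no matching on level. Bootstrap intervals in the closing section resample list members 10000 times and cover the spread between genes only. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.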

Results

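Gene expression was measured in cultured dermal cells of newborn C57BL/6 mice 48 h after transfection with control siRNA (1 array) or siRNA against β-catenin (1 array). β-catenin is a component of adherens junctions and the transcriptional effector of canonical Wnt signalling. The comparison asks which genes differ in these cells when the β-catenin transcript is reduced. The medians of all probe sets were 4.68 on the control array and 4.71 on the β-catenin siRNA array (log2 RMA values). Values of the 2 arrays correlated across the 10197 kept genes with Pearson's r = 0.979, where genes are not independent replicates. There were no replicate arrays, so each difference below is a single subtraction of 2 values, and whether it exceeds the spread between cultures could not be tested.

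The target transcript was lower after β-catenin siRNA. Ctnnb1 had a log2 value of 10.48 on the control array and 9.34 on the β-catenin siRNA array, a difference of -1.14, or 45.2% of the control signal. The robust SD of the difference among genes of similar level was 0.16. Transcripts of other junction proteins differed less in most cases. Of 18 kept genes for catenins and adherens junction proteins, Ctnnb1 and Ctnnd2 (δ-catenin, difference -1.04) were at least 1.5-fold lower. Cdh1, which encodes E-cadherin of epithelial cells and is also in the keratinocyte list, was 1.69-fold higher. Vcl (vinculin) differed by -0.42. The median of this list was -0.09, inside the range of matched random lists (-0.13 to 0.08). Its mean of -0.14 was at percentile 2.04 of random means, but that mean includes the target Ctnnb1 itself.

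Known targets of Wnt/β-catenin signalling were mostly lower. Of 23 kept members of the target list, 16 were lower and 6 higher by any amount, and their median of -0.34 lay below all 10000 random medians (random range -0.12 to 0.10). Over all 33 measured members, without the level filter, the median was -0.19 (percentile 0.04). Genes at least 1.5-fold lower numbered 4. Nkd2 and Nkd1, feedback inhibitors of Wnt signalling, had differences of -0.93 and -0.93, or 1.91-fold and 1.90-fold lower. Axin2, a scaffold of the β-catenin destruction complex and a widely used Wnt reporter gene, was 1.68-fold lower. Some members are named here although they were chosen after their values were seen. Of these, Apcdd1, a membrane-bound Wnt inhibitor and the remaining gene of the 4, was 1.66-fold lower. Ccnd1 (cyclin D1) differed by -0.52, Lgr5 by -0.37, Lef1, which encodes a DNA-binding partner of β-catenin, by -0.09 and Myc by 0.13. The list's only member at least 1.5-fold higher was Sox9, a transcription factor of chondrocytes and hair follicle stem cells, at 2.61-fold higher.

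Wnt ligands and receptors went both ways. Of 9 kept Wnt ligand and R-spondin genes, Wnt2b was 1.93-fold lower and Wnt9a 1.57-fold lower, whereas Rspo3 was 1.89-fold higher and Wnt2 was higher by 0.59 on the log2 scale. The median of -0.34 was at percentile 0.185 of the random lists. It was -0.04 (percentile 34.6) without the level filter, and the mean of the list, -0.16, was at percentile 5.31 of random means. Among 15 receptor genes, 6 were higher and 8 lower by any amount. Fzd4 was 2.04-fold higher and Lgr4 1.79-fold higher. None was at least 1.5-fold lower, though Fzd1 (-0.58) and Ror1 (-0.55) came close. Fzd4 had a control value of 4.20, under the level filter. The receptor median was -0.05 and the mean 0.01. Of 7 kept genes for secreted Wnt inhibitors, Sfrp2 was 2.62-fold higher, Sfrp1 1.91-fold and Frzb 1.79-fold. The median of the inhibitor list was 0.05, inside the random range, and its mean of 0.35 was at percentile 98.9 of random means. The median turned negative with the mean of probe sets, and it was -0.11 (percentile 10.3) over all 17 measured members without the level filter, so the list had no settled direction. None of the 29 kept genes of the cytoplasmic and nuclear Wnt machinery differed by 1.5-fold, and their median was 0.02.

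Across all kept genes, 93 were at least 2-fold higher and 34 at least 2-fold lower after β-catenin siRNA. At 1.5-fold the counts were 281 higher and 188 lower, and 95.4% of kept genes lay within 1.5-fold. Without the level filter, which admits the dimmest probe sets, the 1.5-fold counts were 444 higher and 469 lower. They were 129 and 100 with the stricter filter, and 117 and 53 when 4 robust SDs were required as well. The filter asks only that the higher of the 2 values passes. Control values of Wnt2, Frzb, Lcn2, Lyz2, Sparcl1, Mmp13 and Gdf10, from 4.18 to 5.02, lay under it, as did the β-catenin siRNA values of Ctnnd2, Tnfsf9, Hhip, Lce1h, Camk4 and Hey2, from 4.05 to 5.06, so these folds rest on a dim signal on 1 array.

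**Figure D1:**
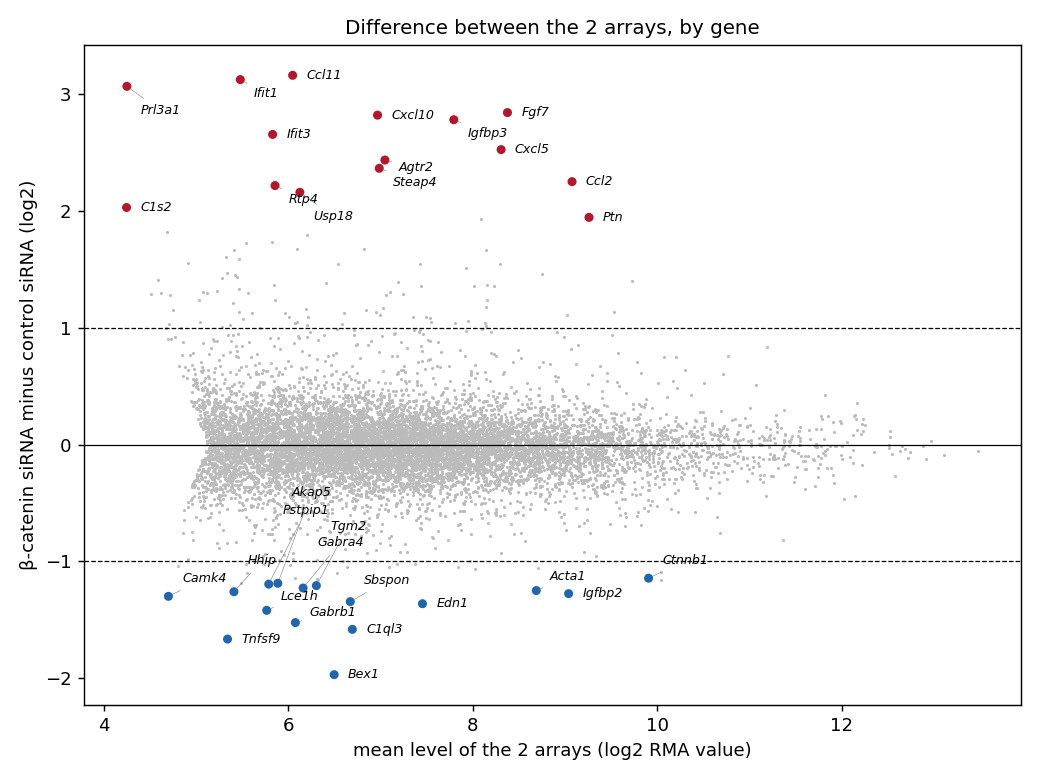
Each grey point is a kept gene, with the mean log2 RMA value of the 2 arrays on the horizontal axis and the β-catenin siRNA minus control siRNA difference (log2) on the vertical axis; dashed lines mark 2-fold, and the 15 most positive (red) and 15 most negative (blue) named genes and Ctnnb1 are labelled. Ctnnb1 lies at -1.14, and Ccl11, Ifit1 and Prl3a1 lie highest, at 3.16, 3.13 and 3.07.

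The 15 largest positive differences included those of several chemokine genes and interferon-stimulated genes. Ccl11, which encodes the eosinophil chemoattractant eotaxin, was 8.96-fold higher, from a control value of 4.47 under the level filter. Fgf7, the keratinocyte growth factor made by dermal fibroblasts and dermal papilla cells, was 7.18-fold higher, from 6.96 to 9.80 on the log2 scale. Igfbp3, a carrier of insulin-like growth factors, was 6.88-fold higher, Agtr2, an angiotensin receptor, 5.42-fold, Steap4, a metalloreductase, 5.16-fold, and Ptn, the heparin-binding growth factor pleiotrophin, 3.85-fold. Prl3a1, a member of the prolactin family, was listed 8.39-fold higher, but its control value of 2.72 was far below the level filter. C1s2, a close relative of C1s1, was 4.09-fold higher, also from a control value of 3.23 under the filter. Probes of such paralogs can share signal, which applies to Ifit1 and Ifit3 as well.

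The largest negative differences were smaller. Bex1, an X-linked gene expressed in brain, was 3.92-fold lower, and Tnfsf9, the ligand of the co-stimulatory receptor 4-1BB, was 3.17-fold lower. C1ql3, a secreted C1q-like protein, differed by -1.58. The GABA-A receptor subunit genes Gabrb1 and Gabra4 were 2.88-fold and 2.34-fold lower. Edn1, which encodes the vasoconstrictor endothelin-1, was 2.57-fold lower, Igfbp2 was 2.42-fold lower, and Tgm2, a protein-crosslinking transglutaminase, was 2.31-fold lower. Hhip, an antagonist of Hedgehog ligands, was 2.40-fold lower. The rest of the 15, Lce1h, Sbspon, Camk4, Acta1, Pstpip1 and Akap5, lay between -1.42 and -1.19.

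Interferon-stimulated genes were higher together. All 26 kept members were higher by some amount, 20 of them by at least 1.5-fold and 17 by at least 2-fold, and none was lower. Their median of 1.23 lay above all 10000 random medians (random range -0.12 to 0.10). Ifit1, an RNA-binding antiviral protein, was 8.73-fold higher, Cxcl10, an interferon-induced T cell chemokine, 7.07-fold, Ifit3 6.31-fold and Rtp4 4.66-fold. Usp18, which limits interferon receptor signalling, was 4.47-fold higher. The control values of Ifit1 (3.92), Ifit3 (4.50), Rtp4 (4.75) and Usp18 (5.05) were below the level filter of 5.13, so their folds rest on a dim control signal. Both cultures were transfected with siRNA, and untransfected cells were not analysed here.

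Many cytokine and chemokine genes were also higher. Of 22 kept cytokine and chemokine genes, 10 were at least 1.5-fold higher and 1 lower, with a median of 0.47 above all random medians. Over all 39 measured members, without the level filter, the median was 0.21, also above all random medians. Cxcl10 was not in this list but in that of interferon-stimulated genes. Within the list, the largest differences after Ccl11 were those of Cxcl5, a neutrophil chemoattractant (5.76-fold), Ccl2, a monocyte chemoattractant (4.77-fold), and Lcn2, an iron-sequestering acute phase protein (2.71-fold). Among only 5 kept complement genes, Serping1 was 2.15-fold higher, C1s1 2.06-fold and Cd55 1.53-fold, and the other 2 were lower by less than 1.5-fold. The complement median of 0.61 was at percentile 99.965, but it was 0.0 (percentile 63.2) without the level filter. A single macrophage and myeloid marker of 27 measured was kept, Lyz2, and it differed by 0.63.

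Genes of the contractile apparatus were lower. Of 32 kept actin and myofibroblast contractile genes, 29 were lower, 8 of them by at least 1.5-fold and none that much higher. The median of -0.37 lay below all random medians (random range -0.11 to 0.05). Acta1, skeletal α-actin, was 2.38-fold lower, Cnn1, the smooth muscle protein calponin, 2.13-fold, Fhl1 1.89-fold and Myl9, a myosin light chain, 1.69-fold. Acta2, the myofibroblast marker α-smooth muscle actin, was chosen after its value was seen and differed by -0.12. The 6 kept pericyte and smooth muscle markers had a median of -0.51, also below all random medians, and all 13 measured markers had a median of -0.32 (percentile 0.01) without the level filter. However, 3 of these 6 genes, and all that were at least 1.5-fold lower, are also in the contractile list.

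Glycolysis and hypoxia genes were lower as well. Of 27 kept members, 21 were lower, 6 by at least 1.5-fold, and the median was -0.39 (random range -0.12 to 0.06). The hypoxia-induced prolyl hydroxylase Egln3 was 2.03-fold lower, Pfkfb3, an activator of glycolysis, 1.99-fold, the lactate exporter Slc16a3 1.74-fold and the glucose transporter Slc2a1 1.62-fold. Smaller shifts in the same direction were found in 3 further lists, in which few or no genes reached 1.5-fold. The median was -0.19 for 32 oxidative phosphorylation genes, -0.21 for 20 cholesterol synthesis and uptake genes and -0.20 for 32 genes of the unfolded protein and amino acid stress response. Of these lists, only the stress response had members at least 1.5-fold lower, Atf3 at 1.70-fold and Ddit4 at 1.66-fold.

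**Figure D2:**
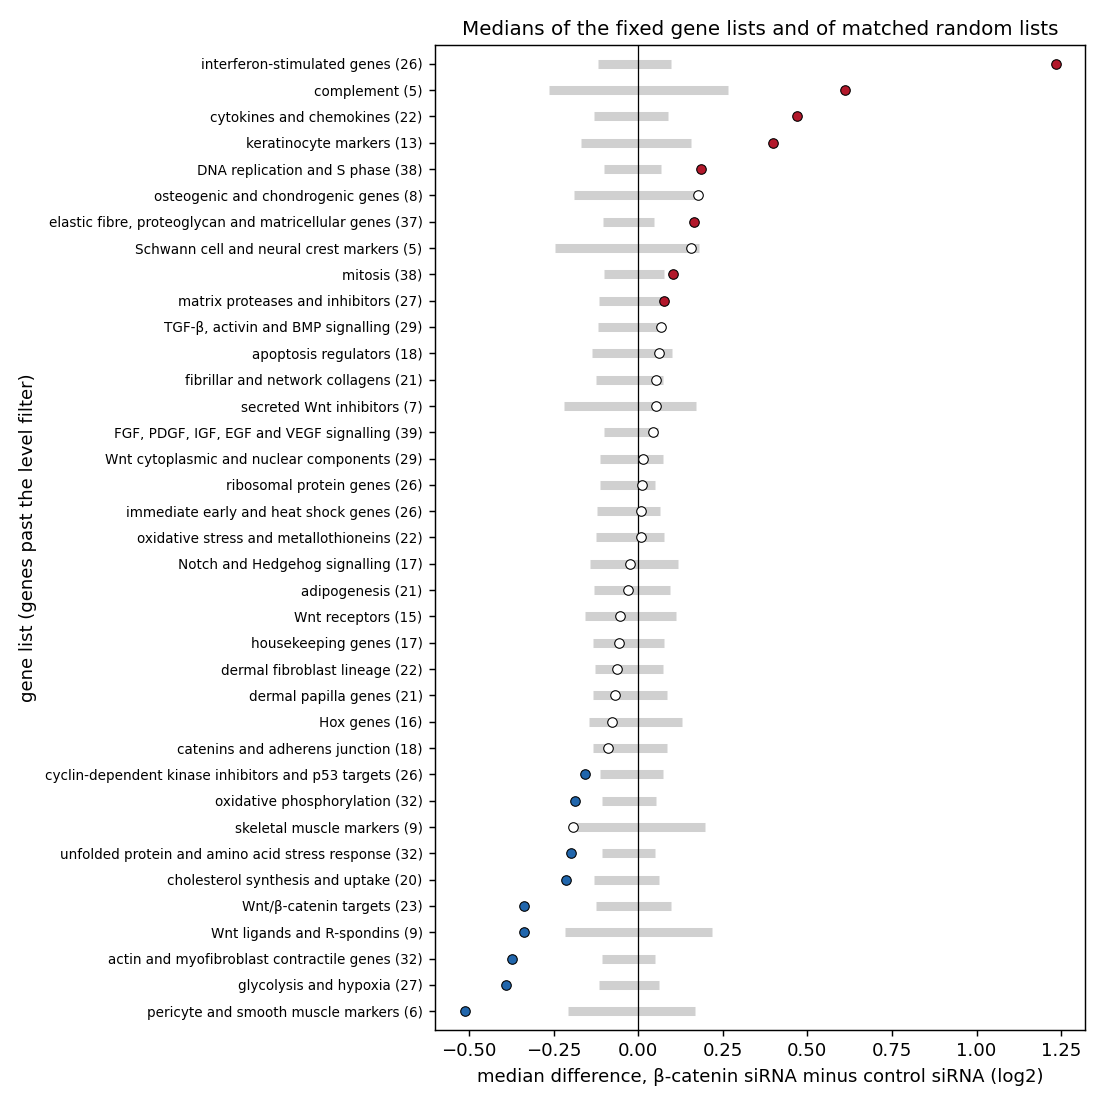
Points give the median β-catenin siRNA minus control siRNA difference (log2, horizontal axis) of each scored gene list, with its number of kept genes in parentheses; grey bars span the central 95% of 10000 random lists matched on level, and filled points lie outside them. Medians ranged from -0.51 (pericyte and smooth muscle markers) to 1.23 (interferon-stimulated genes), and 17 of 37 lists lay outside the bars.

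Cell cycle inhibitor genes held large differences, and DNA replication genes were mostly slightly higher. Among 26 kept genes of the list of cyclin-dependent kinase inhibitors and p53 targets, Cdkn2a and Cdkn2b, which encode inhibitors of the G1 cyclin-dependent kinases, were 2.14-fold and 2.07-fold lower, and the pro-apoptotic gene Pmaip1 was 1.64-fold lower. Cdkn1c, another kinase inhibitor gene, was 1.69-fold higher, and the list's median was -0.16 (percentile 0.25). The 9 kept genes whose symbols begin with Cdkn had a median of -0.06, inside the random range. That group was formed by symbol only and includes Cdkn2aip and Cdkn2aipnl, which are not in the inhibitor list. Of 38 DNA replication and S phase genes, 32 were higher and the median was 0.18, above all random medians, although none reached 1.5-fold. Prim1, a DNA primase subunit, differed by 0.54 and Tyms, thymidylate synthase, by -0.47. Of 38 mitosis genes, 29 were higher with a median of 0.10 (percentile 99.5), and Mki67 differed by 0.53. With the stricter level filter the mitosis median of 0.10 was at percentile 95.7, inside the random range.

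Dermal papilla and fibroblast lineage genes held large differences without a common direction. Of 21 kept dermal papilla genes, 4 were at least 1.5-fold higher, led by Fgf7 and Igfbp3, and 3 at least 1.5-fold lower, led by Hhip. The median of this list was -0.07 and its mean 0.15, and the mean lay outside the range of random means (percentile 98.8). With the stricter level filter the median was -0.26, below the random range, so the direction depended on the setting. Of 22 fibroblast lineage genes, 6 were at least 1.5-fold higher and 1 at least 1.5-fold lower. The higher genes included the proteoglycan gene Lum (2.44-fold), Dlk1 (2.23-fold), Dpt (2.19-fold) and Cd34 (1.97-fold). The median was -0.06 and the mean 0.14, outside the range of random means (percentile 99.2). Of 21 kept adipogenesis genes, 4 were at least 1.5-fold higher, among them the lipoprotein lipase gene Lpl (2.43-fold) and the transcription factor gene Ebf1 (2.06-fold), with a median of -0.03 and a mean of 0.16 (percentile 98.3 of random means). The adipogenesis median was above 0 with the mean of probe sets.

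Several genes for proteoglycans and matrix proteases were higher, and collagen genes differed little. Only 1 of 21 kept collagen genes reached 1.5-fold, Col8a2 at 2.03-fold higher, and the collagen median of 0.05 lay inside the random range (percentile 94.6). The wider family of 33 kept genes whose symbols begin with Col had a median of 0.07, above the random range (percentile 98.1). Elastic fibre, proteoglycan and matricellular genes had a median of 0.17 over 37 genes, above all random medians, and 7 were at least 1.5-fold higher. These included Lum, Dcn (decorin, difference 0.84), Ccn3 (1.75-fold) and Sparcl1 (1.71-fold). Among 27 matrix protease and inhibitor genes, the gelatinase gene Mmp9 was 2.57-fold higher, the collagenase gene Mmp13 2.22-fold and the aggrecanase gene Adamts5 1.96-fold, while the urokinase receptor gene Plaur differed by -0.92. That list's median of 0.07 was at percentile 98.3, and it lay inside the random range with the stricter filter (percentile 94.7) and without matching on level (percentile 96.8).

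Signalling genes outside the Wnt pathway showed single large differences. Jag1, a Notch ligand, was 2.36-fold higher and Hey2, a Notch target, 1.80-fold lower. Inhbb, an activin subunit, was 2.03-fold lower, Tgfb2 1.70-fold lower, Grem1, a BMP antagonist, 1.69-fold lower and Gdf10 1.89-fold higher. The immediate early gene Fosb was 2.24-fold higher. The medians of these lists lay inside the random range, at 0.07 for TGF-β, activin and BMP signalling, -0.02 for Notch and Hedgehog signalling (0.0074 after lowess centring) and 0.01 for immediate early and heat shock genes. The median was 0.04 for FGF and other growth factor signalling, where 6 of 39 genes were at least 1.5-fold higher and 2 lower, and the mean of 0.16 was at percentile 99.9 of random means.

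Markers of other cell types differed too. All 13 kept keratinocyte markers were higher, 5 of them by at least 1.5-fold, with a median of 0.40 at percentile 99.99. Over all 26 measured markers, without the level filter, the median was 0.20, still above the random range. Krt5, a keratin of basal keratinocytes, was 2.02-fold higher, Krt17 1.73-fold, Cdh1 1.69-fold and Krt79 1.54-fold. Outside this list, the cornified envelope gene Lce1h differed by -1.42, and Krt19, a keratin chosen after its value was seen, by -1.05. Few markers of other types were kept. The medians were -0.27 for 3 melanocyte markers and -0.19 for 4 endothelial markers, which were too few to score. For 9 skeletal muscle markers the median was -0.19 (percentile 3.04), against -0.04 (percentile 34.9) over all 30 measured without the level filter, and for 5 Schwann cell and neural crest markers it was 0.16 (percentile 95.8), both inside the random range. A single mast cell marker, Gata2 (-0.43), and a single T cell marker, Thy1 (-0.15), were kept, and fibroblasts also express Thy1. None of the 17 kept housekeeping genes and none of the 26 kept ribosomal protein genes differed by 1.5-fold, with medians of -0.06 and 0.01. The mean of the ribosomal protein genes was -0.0072.

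**Figure D3:**
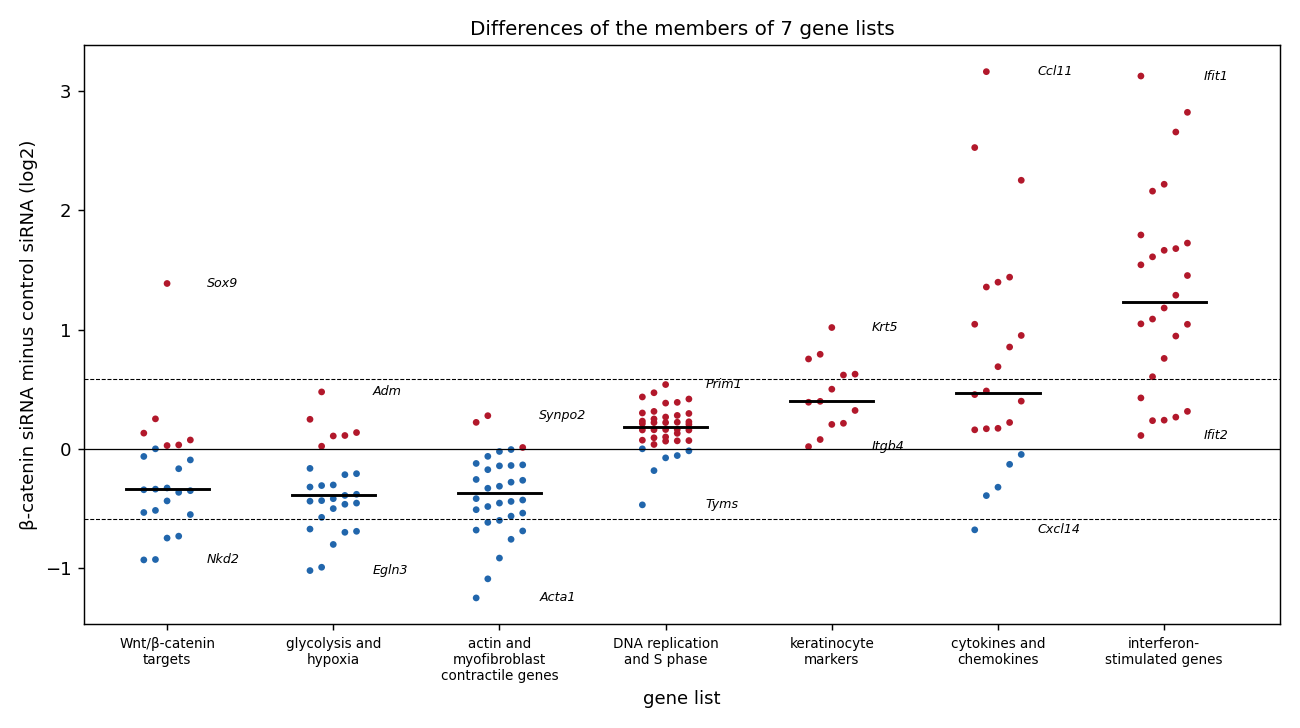
Each point is a kept gene of the list named below it, with its β-catenin siRNA minus control siRNA difference (log2) on the vertical axis (red above 0, blue otherwise); black bars are list medians, dashed lines mark 1.5-fold, and the highest and lowest gene of each list is labelled. All 26 interferon-stimulated genes and all 13 keratinocyte markers lie above 0, and 29 of 32 contractile genes lie below it.

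Of the 37 scored lists, 17 lay outside the random range, 8 above and 9 below, where the nominal rate for independent genes would put 1.85 outside. In the simulation of unchanged genes 7.5% of lists lay outside, which is above that rate. The remaining lists, among them those for apoptosis regulators (median 0.06), oxidative stress and metallothioneins (0.01), Hox genes (-0.08), and osteogenic and chondrogenic genes (0.18), lay inside it. The apoptosis median was -0.12 (percentile 17.0) with the stricter level filter. The osteogenic and chondrogenic value rests on 8 kept genes. Over all 28 measured the median was 0.0 (percentile 67.8), and the mean of the kept genes, 0.35, was at percentile 99.7 of random means. A difference between these 2 arrays cannot be separated from a difference between 2 cultures that would arise without any change in β-catenin.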

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

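All signals below lie in probe sets that the gene comparison did not use, and they were looked at only after the values were seen. Among 1414 probe sets with no gene listed that passed the level filter, 80 were at least 2-fold higher on the β-catenin siRNA array than on the control array and 1 was at least 2-fold lower. These are not 80 independent signals. A group of 50 of them shares 1 identical pair of values, 5.07 on the control array and 6.42 on the β-catenin siRNA array, a difference of 1.35. With identical pairs counted once, 31 were at least 2-fold higher and 1 lower. The largest difference of a probe set with no gene listed was 2.92, from 3.93 to 6.85. Among 746 kept probe sets with several gene symbols, 6 were at least 2-fold higher and 1 lower. Outlying samples and differences between contrasts could not be examined with 1 array per group.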

How the results depend on the processing

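With 2 arrays, precision is limited by their number. No replicate could be left out, and no paired analysis was possible because each group has 1 array. Ctnnb1 was -1.11 after lowess centring and -1.13 after median centring, against -1.14. Its value was exactly the same with the mean of probe sets, so that alternative tests nothing for this gene. The median (or mean) of the Wnt/β-catenin target list stayed between -0.35 and -0.19 and outside the random range under all 8 alternatives that apply to lists. Median centring, 1 of these, shifts list and random medians alike. It cannot change a percentile for any list and is no check on the range. The number of lists outside that range went from 13 (stricter level filter) to 24 (mean of a list), against 17. Counts of genes depended on the level filter by its construction, since it sets how many genes are counted. Without it, 64 genes were at least 2-fold lower, and 444 were higher and 469 lower at 1.5-fold. With the stricter filter the 2-fold counts were 45 higher and 16 lower, and the 1.5-fold counts 129 and 100. Requiring 4 robust SDs as well left 117 higher and 53 lower at 1.5-fold. The 2-fold counts were then 79 and 31. Lowess corrections for kept genes lay between -0.04 and -0.01, so centring moved little. Of the 17 lists outside the random range, 13 stayed outside under every alternative that could score them. The other 4 (Wnt ligands and R-spondins, complement, mitosis, and matrix proteases) entered it in at least 1, and 11 lists left it in at least 1, 8 of them with the mean in place of the median. Skeletal muscle markers left it with the mean of probe sets and with 50 bins, TGF-β signalling without the level filter, and oxidative stress genes with the stricter filter. Osteogenic genes left it with 50 bins and without matching. The cause was not tested. Under lowess centring, median centring and the mean of probe sets, no gene that the naming rule fixed in advance moved by more than the robust SD at its level. Neither centring could have moved a gene that far. The lowess corrections were as small as given above, the median subtracted was -0.018, and the smallest robust SD at any level was 0.16. The mean of probe sets can move only genes with more than 1 probe set. Genes chosen after their values were seen were not recomputed.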

Other observations

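The tests of interferon-stimulated genes outside multigene families, of pericyte markers outside the contractile list and of the number of higher keratinocyte markers, and the use of the size of the lowess curve, were chosen only after the result was seen. Of 160 gene families defined by a shared symbol stem, 11 lay above and 14 below 95% of matched random lists, where the nominal rate would give 8.0. Genes for numbered integrin α subunits (symbols of Itga and a digit, so without letter-named subunits), cell surface receptors for matrix, were lower as a group. Their median was -0.44 over 9 genes, below all random medians, and Itga6 (-0.78) and Itga8 (-0.60) were at least 1.5-fold lower. Keratin genes had a median of 0.36 over 10 genes (percentile 99.97). Of these, 4 were at least 1.5-fold higher, among them Krt5 (2.02-fold) and Krt14 (1.54-fold), and 1 was lower, Krt19 (2.07-fold). The 4 higher genes are also in the keratinocyte list, so their higher level is not a separate observation. Poly(ADP-ribose) polymerase genes had a median of 0.27 over 10 genes, and Parp14, Parp9, Parp10 and Parp12, which are known as interferon-induced members, were higher by 1.61, 1.13, 0.89 and 0.67 on the log2 scale, with the control values of Parp14 (4.52) and Parp10 (4.94) under the level filter. Proteasome β subunit genes were slightly lower as a group (median -0.26 over 9 genes), although Psmb9, also in the interferon-stimulated list, was higher. Mitochondrial ribosomal protein genes of the large subunit (median -0.12 over 47 genes) were slightly lower, and intraflagellar transport genes slightly higher (0.13 over 14 genes). The integrin and polymerase genes, Krt14, Krt19 and Psmb9 were chosen after their values were seen.

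Xist, transcribed from the inactive X chromosome, was 1.55-fold higher after β-catenin siRNA, whereas the Y-linked genes Kdm5d, Eif2s3y and Uty differed by -0.11, -0.05 and -0.05. The 4 sex-linked genes had a median of -0.05 and a mean of 0.11.

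The first pattern is the joint higher level of interferon-stimulated genes. More myeloid cells in the β-catenin siRNA culture cannot be excluded: the median of all 27 measured myeloid markers was -0.050 (bootstrap 95% interval -0.24 to 0.07), against 1.04 for all measured interferon-stimulated genes, but only 1 of the 27 passed the level filter, Lyz2, which was higher by 0.63, from 4.75 to 5.38, and values near the floor cannot decide. The pattern was not confined to the multigene families whose paralogs can share signal, since 18 kept members outside them had a median of 1.11 (interval 0.52 to 1.58). With 20 of the 26 kept members already seen to be at least 1.5-fold higher, that median could not have come out low. It is therefore no independent test of shared signal. An innate response to the particular siRNA duplexes and an effect of losing β-catenin cannot be told apart, because there were 0 arrays of untransfected cells or of a second β-catenin siRNA. Both may contribute, as may a difference between the cultures.

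The second pattern is the lower level of contractile genes. A possible source is a trend of the difference with signal level. The lowess curve on level lay between -0.04 and -0.01 over all kept genes, against a list median of -0.37. Equalised distributions tend to hold such a curve near 0, so its flatness is no independent test. It shows only that the deposited values hold no trend with signal level large enough to account for the median. The median after subtracting that curve was -0.34, which adds no further evidence since so small a curve could not have moved it far. Fewer pericytes or smooth muscle cells in the β-catenin siRNA culture could not be excluded, because only 3 pericyte markers outside the contractile list were kept, with a median of -0.32 (interval -0.42 to 0.20). The lower β-catenin and a difference between the cultures also stay open, as untested.

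The third pattern is the higher level of keratinocyte markers. The same lowess curve, between -0.04 and -0.01, leaves no trend in the deposited values large enough to account for a median of 0.40. The same limit of equalised distributions applies to it. The median after subtracting that curve was 0.41. A larger share of keratinocytes in the β-catenin siRNA culture is a candidate explanation that no value here decides. Outside the list, the cornified envelope gene Lce1h (-1.42) and the keratin gene Krt19 were lower. That 13 of 13 kept markers were higher is the observation that raised it, so it is no independent support, and the highest, Krt5, went from 7.64 to 8.65 while the median over all 26 measured markers was 0.20. The lower β-catenin and a difference between the cultures also stay open, as untested.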
